A study of Homo sapiens with 4 samples.

How the data were processed

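HiCAR libraries had been made from human foreskin fibroblasts (HFF) on hydrogels of 1 kPa (soft) and 50 kPa (stiff), with 2 libraries per surface, per the labels. About 2000000 cells were seeded on soft and 1250000 on stiff, cultured for 20 h and crosslinked, and 200000 cells entered each library, per the labels' protocols. In HiCAR, the transposase Tn5 tags accessible chromatin and restriction enzymes, here MseI and NlaIII per the labels' protocols, cut the rest of the genome, so that each ligation product has an accessible end.

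The authors deposited lists of called interactions at bin widths of 10 and 5 kb, 1 per surface and bin width, so the 2 libraries of a surface are pooled and there are 4 lists. Each line gives 2 anchors on 1 of the 22 autosomes and a score. What the authors' deposited score measures, its scale, the interaction caller and the threshold are not given in the sources used here, and no read counts or error rates stand beside it. The build is GRCh38, per the submitters' processing notes, which also name BWA, FastQC, cutadapt, MACS2, edgeR, Juicer and bedtools without versions or roles. Read depth per library is therefore unknown, and the number of called interactions can move with depth.

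The score was checked on the files. Interactions with equal scores were exactly the connected clusters of neighbouring bin pairs (within 1 bin at 10 kb and within 3 bins at 5 kb), with 0 neighbouring pairs of different score. The score was therefore treated as a value of the cluster and used only to rank or filter interactions within 1 list. A comparison of strength between surfaces, planned for interactions on identical bins, was left out because nothing makes the scores of the lists comparable, and with it the choice of single interactions by change in strength.

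An interaction had a partner in the other list when both anchors lay within 1 bin, and a cluster when any of its bin pairs had one. Chance was measured by 1000 random placements that kept chromosome and span, and by shifts of both anchors by 200 kb to 1 Mb. Span is the distance between anchor midpoints. Counts carry exact Poisson and shares exact Clopper-Pearson 95% intervals, and ratios of 2 counts an interval from the exact binomial share. Neighbouring bin pairs and PCR copies are not independent, and these intervals cover counting error only.

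Genes came from a RefSeq gene table on GRCh38 with chromosome, start and end, which gives 19126 protein-coding genes on the autosomes. It gives no strand, so the planned use of the 5' end was replaced by either annotated end of the gene inside the anchor bin. An interaction counted for a gene when an anchor held such an end. Classes of interactions by gene ends were set against 100 random placements. Gene lists were compared by the mean of stiff minus soft interactions per gene, as a percentile among 10000 random lists of the same size, drawn from strata of 0, 1, 2, 3 to 4, 5 to 7 and 8 or more interactions over both surfaces. No test between surfaces was run, because each surface has 1 list, and no p-value is given.

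The genes named followed a rule fixed, like the 17 gene lists, before the data were examined: the 10 genes with the largest difference in each direction, up to 4 members of each list with the largest difference and the member with most interactions, and the 3 clusters of highest score without a partner in each list, the score standing in for an error rate the lists do not give. Genes with ends in the same bin are 1 entry. A few items that the rule takes are not reported here.

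Alternatives were the 5 kb lists, lists of equal length by score, clusters as units, each chromosome left out, spans up to 1 Mb, identical bins, a tolerance of 2 bins, anchors extended by 5 kb, all annotated genes, unmatched random lists and soft counts scaled to the stiff total. A score of at least 20, any part of a gene in the anchor, and only interactions without a partner were added after the data were seen. The matching and the percentiles were run on simulated data. Simulated lists of 9686 interactions made with 24.9, 49.9 and 75.6% matched gave 25.3, 50.2 and 75.6%. Their matched interactions had been moved by at most 1 bin, the tolerance itself, so this checks the code and not the choice of tolerance. Unplanted lists of 20 genes, all with at least 2 interactions over both surfaces, lay outside the limits in 7% of draws. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.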

Results

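Chromatin contacts anchored at open regulatory DNA were mapped by HiCAR in HFF cells, human foreskin fibroblasts, that had been cultured for 20 h on a soft hydrogel of 1 kPa or a stiff hydrogel of 50 kPa. HiCAR (Hi-C on accessible regulatory DNA) joins Tn5 tagging of open chromatin to proximity ligation, so each recorded contact has an accessible anchor. There were 2 libraries of 200000 crosslinked cells per surface, and the analysed files hold 1 list of called interactions per surface at each of 2 resolutions, with the libraries of a surface pooled. No surface therefore has a replicate value, no test between surfaces could be run, and every interval below is a 95% interval that covers counting error only. Neighbouring 10 kb bin pairs belong to the same contact, so these intervals, which treat them as independent, are too narrow. Read depth is unknown, since the lists give a score per interaction and no read counts.

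The question was whether the stiffness of the surface alters the folding of chromatin, and most strong contacts were found on both surfaces. The cyclin D1 gene CCND1, a driver of entry into the cell cycle, touched 15 interactions on soft and 16 on stiff, and THBS1, which encodes the matrix protein thrombospondin-1, touched 16 on each. ZFP36L1, an RNA-binding regulator of mRNA decay, touched 22 on soft and 18 on stiff. The gene of the transcription factor SNAI2 (Slug), known for its part in epithelial-mesenchymal transition, touched 26 and 19. Similar counts need not be the same contacts. On soft and stiff, 1 and 2 interactions of CCND1 had no partner within 1 bin in the other list. The numbers were 4 and 0 for THBS1, 4 and 3 for ZFP36L1 and 8 and 3 for SNAI2.

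Over all 22 autosomes, 9686 interactions (95% Poisson interval 9494 to 9881) were called at 10 kb on soft and 9017 (8832 to 9205) on stiff, a stiff over soft ratio of 0.931 (0.905 to 0.958). Grouped into clusters of neighbouring bin pairs, they came to 4139 on soft and 3968 on stiff, a ratio of 0.959 (0.918 to 1.002). That interval holds 1. Fewer interactions were called on stiff on 19 of the 22 chromosomes. The exceptions were chromosomes 3, 4 and 13, of which chromosome 4 had 197 on soft and 243 on stiff, a ratio of 1.23 (1.02 to 1.5). Its ratio in clusters was 1.28 (0.968 to 1.70). Counted in clusters, chromosomes 3, 4, 5, 12 and 22 had more on stiff. The 5 kb lists were shorter, with 1141 interactions on soft and 968 on stiff.

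Of the soft interactions, 6584 (68.0%, exact binomial interval 67.0 to 68.9) had a partner in the stiff list with both anchors within 1 bin, and of the stiff interactions 6370 (70.6%, 69.7 to 71.6) had a partner in the soft list. Interactions placed at random on the same chromosome with the same span gave 0.489% and 0.518% on average over 1000 placements, and interactions shifted nearby gave 0.915% and 0.968%. The share rose with the authors' score. A cluster counted as having a partner when any of its bin pairs had one, and cluster size was not held equal between the quintiles. In the soft list 26.2% (23.2 to 29.3) of the clusters in the lowest quintile of scores had a partner and 95.3% (93.6 to 96.6) in the highest quintile. The corresponding shares of the stiff list were 29.7% (26.6 to 33.0) and 96.6% (95.1 to 97.7). Soft interactions without a partner at 10 kb were found in the soft 5 kb list in 2.71% of cases (2.17 to 3.34) and in the stiff 5 kb list in 0.129% (0.0351 to 0.330). For stiff interactions without a partner the shares were 2.87% (2.27 to 3.58) in the stiff 5 kb list and 0.113% (0.0234 to 0.331) in the soft 5 kb list. The 5 and 10 kb lists of a surface come from the same libraries, and these interactions were chosen for lacking a partner. The lower share in the other surface's 5 kb list follows largely from that choice and is no independent support. Interactions with a partner were found at 5 kb more often, in 12.5% of cases in the soft and 9.74% in the stiff 5 kb list for those of the soft 10 kb list, and in 11.7% and 11.1% for those of the stiff 10 kb list.

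**Figure D1:**
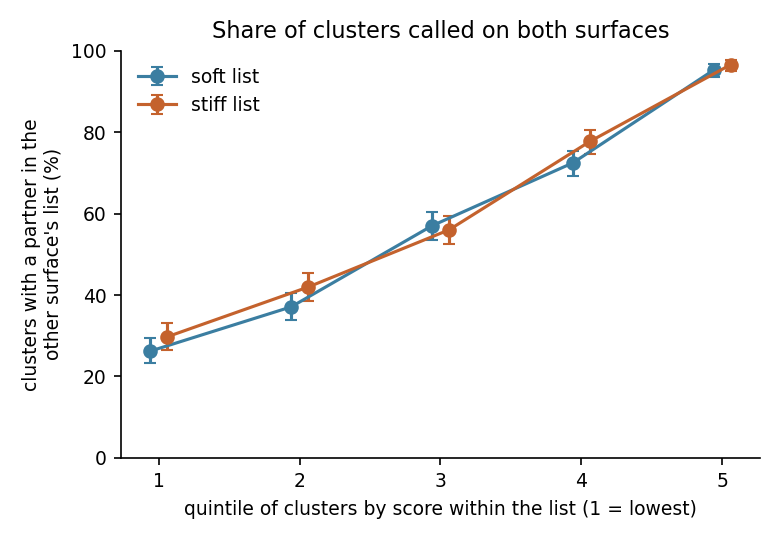
Share of clusters with a partner in the other surface's list (vertical axis, percent) by quintile of the score within each list (horizontal axis, 1 lowest) for the soft and the stiff 10 kb list, with exact 95% binomial intervals that cover counting error only. The share was 26.2% in the lowest and 95.3% in the highest quintile of the soft list, and 29.7% and 96.6% in the stiff list.

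Among clusters without a partner, those with the highest scores in each list were singled out. On soft, the first joined positions 14200001 to 14230000 and 14700001 to 14760000 of chromosome 6 (GRCh38), where neither anchor holds an end of a protein-coding gene. It had a score of 62.9 within the soft list, 7 bin pairs, and 3 calls in the soft against 0 in the stiff 5 kb list. The 5 kb lists come from the same libraries and are no independent support. The second joined an anchor with an end of SLC25A26, the mitochondrial S-adenosylmethionine carrier, at 66250001 to 66280000 of chromosome 3 to 66820001 to 66840000 (score 60.7). This second soft cluster had 0 calls in either 5 kb list. On stiff, a cluster joined the bins of EEF1A1 and MTO1 at 73500001 to 73530000 of chromosome 6 to SLC17A5 at 73580001 to 73620000 (score 48.3). Another joined ECHDC2 and SCP2 at 52900001 to 52940000 of chromosome 1 to 53170001 to 53190000 (score 46.8). Neither of these stiff clusters had a call in either 5 kb list, and scores of the 2 lists were not set against each other.

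Long contacts were fewer on stiff. At IGFBP3, which encodes a binding protein of insulin-like growth factors, the median span was 1160 kb over 9 interactions on soft and 440 kb over 5 on stiff, and 6 and 2 of them spanned over 1 Mb. JUN, an AP-1 subunit gene, went the other way, with 635 kb over 6 interactions on soft and 910 kb over 9 on stiff, and at SNAI2 the medians were 495 and 500 kb. Over the whole lists the median span was 220 kb on soft (quartiles 140 and 340) and 210 kb on stiff (140 and 320), a difference of 1 bin. Interactions without a partner had a median span of 230 kb (140 to 380) on soft and 200 kb (130 to 320) on stiff. Classes of span, chosen after the spans had been seen, gave 3166 interactions on soft and 3147 on stiff between 100 and 200 kb, a ratio of 0.994 (0.946 to 1.04). Between 400 and 600 kb there were 1132 and 927, a ratio of 0.819 (0.75 to 0.894), and between 600 kb and 1 Mb 459 and 311, a ratio of 0.678 (0.585 to 0.784). Between 1 and 2 Mb there were 118 and 63, a ratio of 0.534 (0.387 to 0.731). Over 2 Mb there were 13 and 14.

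**Figure D2:**
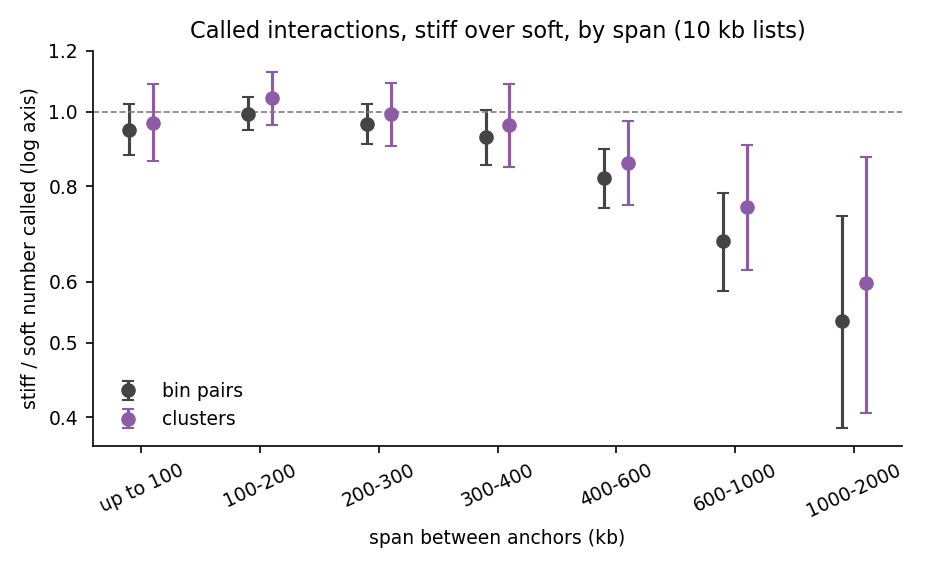
Number of called 10 kb interactions on stiff over soft (vertical log axis, no unit) by span between the anchors (horizontal axis, kb), for bin pairs and for clusters, with 95% intervals that cover counting error only and a dashed line at 1. The ratio for bin pairs was 0.994 between 100 and 200 kb, 0.678 between 600 and 1000 kb and 0.534 between 1000 and 2000 kb.

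Promoter-sized anchors were compared next, with an anchor counted at a gene when its 10 kb bin held either annotated end of a protein-coding gene. On soft 35.6% of interactions (34.7 to 36.6) had a gene end in 1 anchor and 5.84% (5.38 to 6.33) in both. On stiff the shares were 37.2% (36.2 to 38.2) and 5.58% (5.11 to 6.07). Randomly placed interactions of the same spans gave 17.7% and 2.53% for the soft list and 17.5% and 2.46% for the stiff list. These placements were uniform along each chromosome and did not require an accessible anchor, as HiCAR does. The excess over them can therefore not be read as a preference of contacts for genes. Examples with gene ends in both anchors were BOD1 with STC2 on soft and TES with CAV1 on both surfaces. The soft cluster of BOD1 with STC2 also had a stiff partner, through other bin pairs. The gene table used gives no strand, so the start of transcription could not be told from the other end of the gene.

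Interactions per gene were compared for 19126 protein-coding genes. The gene of vimentin, VIM, the intermediate filament protein of mesenchymal cells, touched 4 interactions on soft and 11 on stiff, and KLF6, a zinc-finger transcription factor gene, touched 6 and 12. CITED2, which encodes a coregulator that binds CBP and p300, had none on soft and 5 on stiff. Its clusters scored 14.9, 9.23 and 15.7, no higher than the middle quintile of the stiff list. In the opposite direction, PHLDA1 touched 13 on soft and 5 on stiff, and SNAI2 26 and 19. Of the 3415 genes with an interaction, 1713 had at least 1 on both surfaces, 887 on soft alone and 815 on stiff alone. Of the 3415, 1266 touched only 1 interaction over both lists. A gene with calls on 1 surface alone can still touch an interaction with a partner within 1 bin, as FHL2 did with 1 on soft. More interactions were called on stiff for 1274 genes, fewer for 1411, and the number was equal for 730. With the lists cut to equal length by score, the direction turned, with more on stiff for 1348 genes and fewer for 1246.

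The 10 largest differences toward stiff were followed gene by gene. KRTAP2-3, at 41059240 to 41060114 of chromosome 17, shares a bin with each of KRTAP2-2 and KRTAP2-4, all genes of keratin-associated proteins. KRTAP2-3 touched 2 interactions on soft and 9 on stiff, and 6 of the 9 had no partner on soft. Some of these reached bins of the hair keratin genes KRT34 and KRT31. VIM lies at 17228241 to 17237593 of chromosome 10, and 10 of its 11 stiff interactions had a soft partner, so that the difference came from wider clusters (3 on soft, 4 on stiff). AP3M2 shared a bin with PLAT, the gene of tissue plasminogen activator, and touched 5 and 12. Of the 12 stiff interactions of KLF6 (3775996 to 3785209 of chromosome 10), 7 had no soft partner, while all 6 on soft had a stiff partner. IRF2BP2, a transcriptional corepressor gene, touched 18 and 24. TES, which encodes the focal adhesion protein testin, touched 5 and 10, and its interactions on both surfaces reached bins of CAV1 and CAV2, the caveolin genes. BCAR3, the gene of an adaptor that binds the focal adhesion protein BCAR1, touched 5 and 10, with 6 of the 10 lacking a soft partner. BMP6, which shares a bin with TXNDC5, touched 3 and 8. All of them lay at 7720001 to 7730000, the bin of 1 end of BMP6, so they need not be interactions of TXNDC5. EEF1A1, which encodes a translation elongation factor, had none on soft and 5 on stiff, all in 1 cluster.

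Among the 10 largest differences toward soft, BOD1, whose product acts in chromosome biorientation, touched 9 interactions on soft and 1 on stiff. Of these, 6 without a stiff partner joined bins 173600001 to 173620000 of chromosome 5 to 173280001 to 173330000, which hold an end of STC2, the gene of stanniocalcin-2. Their cluster had a score of 156, above 62.9, the highest of the soft clusters without a partner. Other bin pairs of that cluster therefore had a stiff partner, and the contact is not one of soft alone. PHLDA1, which shares a bin with NAP1L1, had 5 clusters on soft and 3 on stiff. CDKN2AIPNL touched 8 and 1, FAM91A1 11 and 5, the sorting nexin gene SNX18 10 and 4, and TMED10 7 and 2. LIPA, the gene of lysosomal acid lipase, touched 7 and 1, and 1 of the soft interactions reached a bin of ACTA2. LIPA shares a bin with IFIT5. Only 1 soft interaction lay at the end of LIPA in 89410001 to 89420000, and the others lay at the end in 89210001 to 89220000. Not all of them are therefore interactions of IFIT5. IL1R2, the decoy receptor of interleukin-1, touched 11 and 6, with interactions to a bin of IL1RL2 on both surfaces and to bins of IL1R1 on soft. SNAI2 had 8 clusters on each surface, not all of them matched, and 8 of its 26 soft interactions had no stiff partner against 3 of the 19 on stiff.

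**Figure D3:**
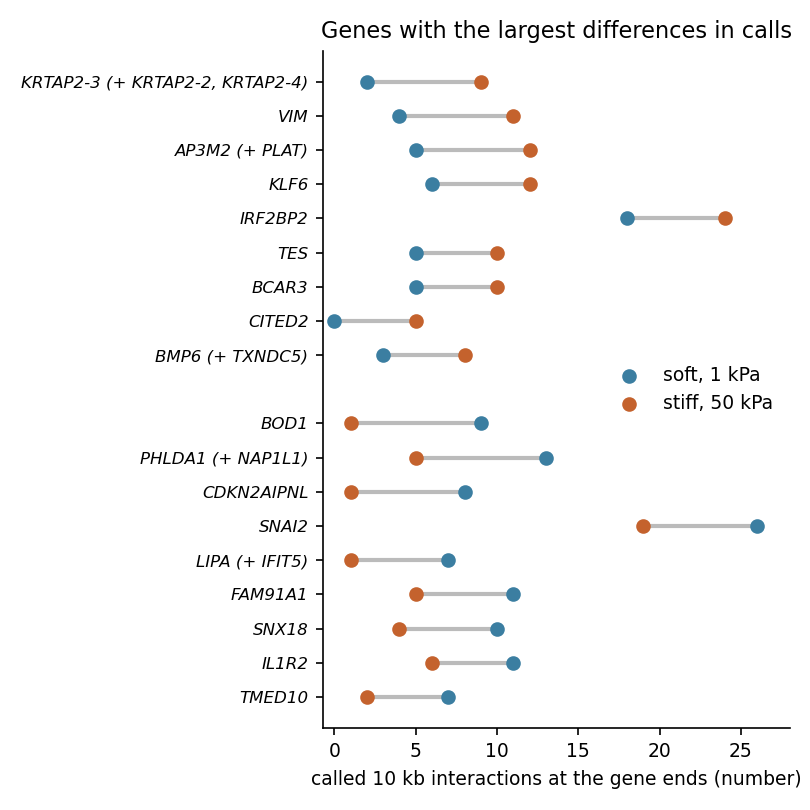
Number of called 10 kb interactions at the ends of each gene (horizontal axis) on soft and on stiff for the 9 genes with the largest difference in each direction, 1 list per surface and no error bars. VIM had 4 on soft and 11 on stiff, and BOD1 9 and 1. Genes in brackets share at least 1 bin with the named gene and need not touch all its interactions.

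**Figure D4:**
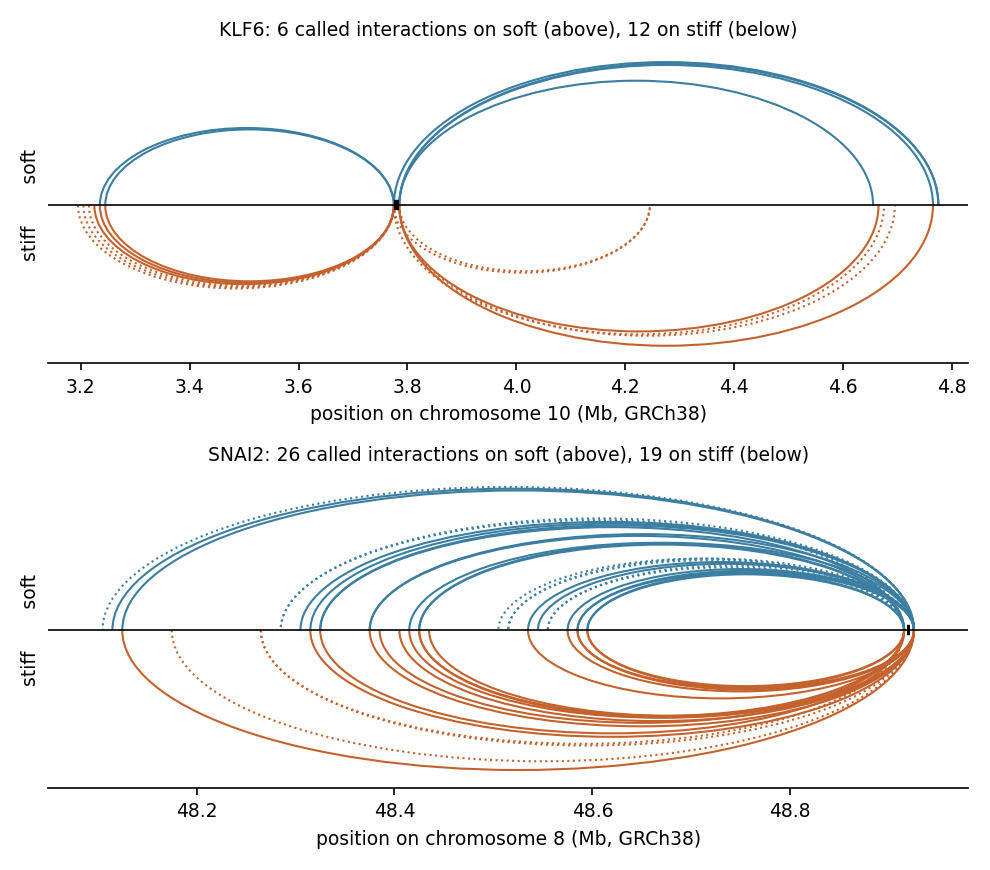
Called 10 kb interactions at KLF6 and SNAI2 drawn as arcs between the anchor midpoints (horizontal axis, Mb on GRCh38), soft above and stiff below the line; dotted arcs have no partner within 1 bin on the other surface, the black bar is the gene, and arc height follows span. KLF6 had 6 arcs on soft and 12 on stiff, and SNAI2 26 and 19.

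In all, 80 genes differed by at least 4 interactions, 41 with more on stiff and 39 with fewer. When the labels of the 2 surfaces were swapped at random for each cluster, which keeps the difference within a cluster, 71.2 genes did so on average over 1000 swaps, with a central 95% range of 58.0 to 85.0, and 23 of the 80 had a cluster that differed by at least 4 alone. Counted in clusters, AP3M2 and TES had 1 more on soft, and in the 5 kb lists IRF2BP2, AP3M2, FAM91A1 and SNX18 differed in the opposite direction.

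The lists of genes fixed before the data were examined were compared through the mean of stiff minus soft interactions per gene, as its percentile among 10000 random lists of the same size matched on the interactions of both surfaces. Among targets of YAP/TAZ and TEAD, coactivators and their DNA-binding partners that are known to respond to stiffness, 5 of the 15 genes with an interaction had more on stiff and 8 had fewer, with 45 interactions on soft and 35 on stiff (percentile 11.1). The percentile lay on the opposite side of the middle in the 5 kb lists, at 84.8, and with any part of the gene in the anchor, at 74.98. MYOF, a membrane repair gene, had 5 on soft and none on stiff at 10 kb, but 2 on each surface at 5 kb. IGFBP3 had 9 and 5, F3, which encodes tissue factor, 6 and 4, and AMOTL2, the gene of an angiomotin that binds YAP, 1 and 4. The canonical target CCN2, named after its values were seen, had 4 and 3.

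Genes of the actin cytoskeleton and targets of SRF and MRTF had 21 interactions on soft and 16 on stiff (percentile 17.5), with more on stiff for 2 and fewer for 4 of 9 genes. The tropomyosin gene TPM1 had 8 and 5, ACTA2, the gene of smooth muscle actin, 4 and 2, ACTG1 none and 1, and MRTFA 1 and 2. Integrin and focal adhesion genes had 23 and 18 (percentile 20.4), with more on stiff for 3 and fewer for 4 of 10 genes, and a percentile of 54.9 in clusters. The hyaluronan receptor gene CD44 had 5 and 1, ITGB3 2 and none, ITGB5 5 and 6 and the caveolin gene CAV1 3 and 4. All 5 soft interactions of CD44 had a stiff partner, and with any part of the gene in the anchor CD44 had 17 and 16.

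Extracellular matrix genes had 52 interactions on soft and 56 on stiff (percentile 79.9), with more on stiff for 6 and fewer for 5 of 16 genes. In clusters they had 27 and 22 (percentile 12.9), and unmatched interactions alone gave a percentile of 17.5, both in the opposite direction. The collagen genes COL5A1 and COL6A3 had 1 and 4, and none and 3. TNC, which encodes tenascin-C, had 6 and 9, although it had 1 cluster fewer on stiff, while ELN, the gene of elastin, had 3 and none. For the AP-1 family the numbers were 16 and 18 (percentile 75.3). JUN had 6 and 9, although it had 1 cluster fewer on stiff, FOSL2 7 on each surface, FOS 2 and 1 and FOSB 1 on each. Genes of the TGF-beta pathway had 23 and 17 (percentile 17.0), with more on stiff for 4 and fewer for 8 of 14 genes, but a percentile of 77.4 with anchors extended by 5 kb and 85.2 with any part of the gene. BAMBI, a decoy receptor gene, had 3 and 1, TGIF1 2 and none, TGFBR1 3 and 2, SMAD7 2 and 3, and INHBA 5 on each.

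Genes of the nuclear lamina and the LINC complex had 4 interactions on soft and 7 on stiff (percentile 88.0), but lay at percentile 16.4 in the 5 kb lists. LMNA, which encodes the A-type lamins, had 2 and 4, LMNB2 1 and 2 and SUN1 1 on each. Mesenchymal and mechanosensitive transcription factors had 57 and 54 (percentile 42.5). KLF4 had 1 and 5 and KLF6 6 and 12, while WWTR1, the gene of TAZ, had 4 and none. Inflammatory and matrix-degrading genes had 15 and 9 (percentile 8.57), with more on stiff for 2 and fewer for 6 of 9 genes. NFKBIA, the gene of an inhibitor of NF-kappa-B, had 3 and 1 and TNFAIP3 2 and none. IL6 had 2 and 3 and ICAM1 3 and 2.

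Cell cycle genes had 27 and 30 interactions (percentile 78.8), with CDK6 at 5 and 4, CDKN1B at 1 and 2 and AURKA at 1 and 2. Adipogenic and quiescence genes had 31 on each surface (percentile 55.3), with CEBPD and CDKN1C at 1 and 4 each and CEBPB at 3 and 2. Housekeeping genes had 8 and 7 (percentile 44.7), but 7 and 3 when counted in clusters. Among them were EEF1A1, YWHAZ at 2 and none, TUBB at 2 and none and ACTR3 at 2 and 1.

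Markers of other cell types touched few interactions on either surface. An interaction was found at 2 of 10 keratinocyte, 2 of 9 endothelial, 1 of 10 blood, 0 of 8 melanocyte and 2 of 8 mural genes. Among all 19126 genes 3415 had one, so this does not set these markers apart. Keratinocyte genes had 4 and 3 (percentile 32.4), from KRT10 and EPCAM, endothelial genes 3 and 2 (percentile 35.0), from PECAM1 and ERG, and mural cell genes 2 and 3 (percentile 72.5), from RGS5 and NOTCH3. Blood genes had none and 1 (percentile 75.4), at LYZ, and melanocyte genes had none on either surface. No list lay outside the central 95% of its matched random lists. Against random lists not matched on interactions, which hold mostly genes without one, the percentile was 0.280 for YAP/TAZ-TEAD targets, 1.98 for the TGF-beta pathway and 2.16 for inflammatory genes. Actin genes lay at 99.1 in the 5 kb lists and, in the opposite direction, at 0.340 with any part of the gene in the anchor. A simulated list of 20 genes with 3 of 4 interactions on 1 surface lay above the central 95% in 99% of draws. All its genes had at least 2 interactions over both surfaces, drawn independently of each other. The lists above hold many genes without an interaction and interactions that come in clusters, so the 99% does not carry over to them.

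**Figure D5:**
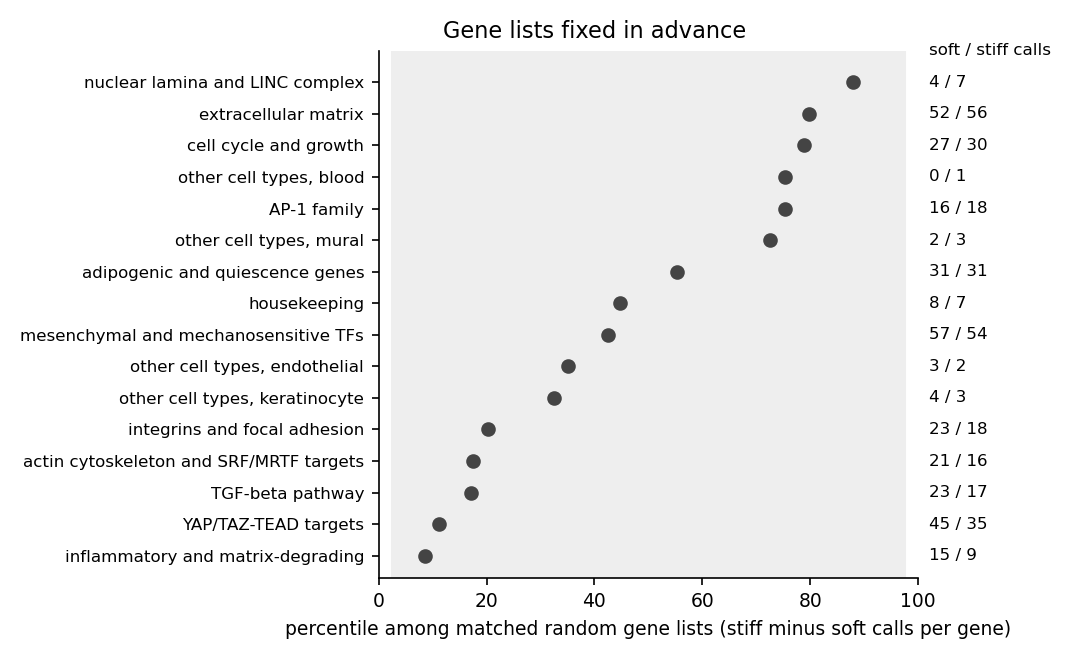
Percentile of each gene list's mean stiff minus soft number of interactions per gene among 10000 matched random lists (horizontal axis, 0 to 100), with the central 95% shaded and the soft and stiff interactions at right, for the 16 lists with an interaction. The percentiles run from 8.57 for inflammatory and matrix-degrading genes to 88.0 for genes of the nuclear lamina and LINC complex.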

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

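No paired analysis was possible because the lists pool the libraries of each surface, and for the same reason no library was left out in turn. A stricter error rate, a minimum of 20 reads, observed reads and transcript 5' ends could not be tried, since neither reads, error rates nor strand are in the sources used here, the strength of interactions was not compared, and no interaction lay on X. Alternatives at a score of 20, with any part of a gene and with unmatched interactions alone were chosen after the data were seen.

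Fewer interactions on stiff were found under each alternative except equal list lengths, which fix the ratio at 1. In clusters the interval of the ratio held 1, both at 10 kb (0.918 to 1.002) and at 5 kb (0.897, 0.802 to 1.003). The 5 kb lists held 1141 and 968 (ratio 0.848), clusters numbered 4139 and 3968 (0.959), and 5445 and 4942 interactions had a score of at least 20, a limit set on each list that also removes partners scored below it. The matched shares of the soft and stiff list were 44.6% and 49.4% at 5 kb, 71.2% and 68.1% with equal lengths, 57.6% and 60.4% in clusters, 43.5% and 46.7% on identical bins and 74.4% and 76.1% within 2 bins, and 66.8% of the soft list with a score of at least 20. The median span was 160 and 150 kb at 5 kb, 225 and 215 kb in clusters, and as low as 200 kb on stiff with 1 chromosome left out. The share with a gene end in an anchor, 41.5% on soft and 42.8% on stiff, was 30.1% and 28.1% at 5 kb, 53.1% and 54.0% in clusters, 60.1% and 61.4% with anchors extended by 5 kb, 64.2% and 65.7% with all annotated genes and 84.1% and 84.8% with any part of a gene. Genes with more and fewer interactions on stiff numbered 166 and 225 at 5 kb and 621 and 813 at a score of at least 20. With equal list lengths the order turned, to 1348 with more and 1246 with fewer. Scaling the soft counts to the stiff total gave 2004 with more, since equal counts then become higher ones on stiff.

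Against random lists not matched on the number of interactions, the percentile was 0.280 for YAP/TAZ-TEAD targets, 1.98 for the TGF-beta pathway and 2.16 for inflammatory genes. Such random lists hold mostly genes without an interaction, since 3415 of 19126 genes have one, against 15 of 24 YAP/TAZ-TEAD targets. These percentiles therefore compare unlike lists. Actin genes lay at 99.1 in the 5 kb lists and at 0.340 with any part of the gene, in opposite directions. Other lists moved across the middle within their random range: YAP/TAZ-TEAD targets to 84.8 in the 5 kb lists and 74.98 with any part of the gene, extracellular matrix genes to 12.9 in clusters and 17.5 with unmatched interactions alone, lamina and LINC genes to 16.4 in the 5 kb lists, integrin genes to 73.2 and the TGF-beta pathway to 85.2 with any part of the gene, and cell cycle genes to 32.9 and the TGF-beta pathway to 65.5 at a score of at least 20. The cause of the other moves was not tested.

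Differences (stiff minus soft) of named genes turned in sign as follows, and the cause was not tested. In the 5 kb lists, AP3M2, ITGB5, TNC and LMNB2 had -1 and IRF2BP2 -4, while FAM91A1, SNX18, F3, IGFBP3 and ACTA2 had 1. In clusters, AP3M2, TES, TNC and JUN had -1 and TGFBR1 had 1. At a score of at least 20, which leaves no soft call of TPM1 although scores of the lists cannot be set against each other, TPM1 had 5 and CAV1 and CCND1 -1. With anchors extended by 5 kb, MRTFA had -1 and PECAM1 and ACTR3 1, and with any part of the gene MRTFA had -5, COL5A1 -3 and ACTR3 2. Of the 20 genes with the largest differences, 20 kept their direction with extended anchors, equal lengths or spans up to 1 Mb, 15 in clusters, 19 of the 19 with a call at a score of at least 20 and 6 of the 11 with a call in the 5 kb lists. CITED2 had no call at a score of at least 20.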

Other observations

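Among the 15 genes with most interactions over both surfaces, chosen after their values were seen, TBX3, a T-box transcription factor gene of limb and skin development, led with 28 on soft and 26 on stiff. LOC124903470, which shares a bin with THBS1, had 28 and 23. These include the 16 on each surface of THBS1, all of which lay at the shared bin. Of the 28 on soft, 7 had no stiff partner, against 0 on stiff. HIC1, a transcriptional repressor gene that shares a bin with SMG6, had 20 and 18. The polo-like kinase gene PLK2 had 15 and 12, SLC45A1 15 and 12, and ZFP36L2, a relative of ZFP36L1, 16 and 11. The forkhead genes FOXC2 and FOXL1, neighbours on chromosome 16, had 13 on each surface and 11 and 15. IGFBP5 had 11 and 13, SRP9, which encodes a subunit of the signal recognition particle, 11 and 12, and ERRFI1, which encodes an inhibitor of the EGF receptor, 11 on each.

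Of contacts between 1 and 2 Mb long, TBX3, again chosen after its values were seen like the other genes here, had 7 on soft and 4 on stiff, IGFBP3 6 and 2, PLK2 4 and 1, and ID2, an inhibitor of basic helix-loop-helix factors, 3 and 0. KLF4 and IGFBP5 went the other way, with 1 and 4 and with 2 and 4. The histone genes of chromosome 6 were joined over up to 1.86 Mb on soft and 1.83 Mb on stiff, for example at H2AC4 and H3C2 with 1 on soft and 3 on stiff, and at H2AC15 and H4C12 with 3 and 1.

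The tests of clusters over 600 kb by number, of gene families at contacts over 2 Mb and of genes with many more calls on 1 surface were chosen after the result was seen. The other tests below were set before.

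Contacts longer than 600 kb and up to 2 Mb, such as those of IGFBP3 and PLK2, were fewer on stiff, with 577 on soft and 374 on stiff. The ratio was 0.648 (0.568 to 0.740), against 0.949 (0.921 to 0.977) at shorter spans. In the 5 kb lists there were 33 and 16, a ratio of 0.485 (0.249 to 0.906). That interval holds the 5 kb ratio at shorter spans, 0.859 from 1100 and 945. A few wide clusters do not account for the fewer long contacts at 10 kb, since the ratio in clusters was 0.716 (0.605 to 0.847). Nor do a few chromosomes, since the ratio was lower above 600 kb than below on 19 of 22. The ratio in clusters over 600 kb stayed between 0.687 and 0.731 with any chromosome left out. Soft clusters over 600 kb had a stiff partner less often than shorter ones within the same quintiles of the score. The difference was -14.2 percentage points (bootstrap interval -18.9 to -8.86), and 2.26 (-3.45 to 8.0) for stiff clusters. This argues against a lower depth or a higher threshold on stiff only if clusters of equal score are lost alike at each span. What the score measures is unknown and cluster size was not held equal, so that cannot be taken as given. A lower depth or a higher threshold on stiff that acts more on long contacts therefore stays open. So do a library whose read pairs reach less far, the different seeding of 2000000 and 1250000 cells and stiffness itself. These cannot be separated with 1 pooled list per surface. A hypothesis that stiff surfaces shorten the reach of contacts may be worth a test on replicate contact maps.

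Contacts over 2 Mb formed 14 clusters, of which 8 were called on both surfaces, 3 on soft alone and 3 on stiff alone. In 4 of the 14 both anchors held genes whose symbols share most of their letters: KRTAP5-2 with KRTAP5-10 over 69.97 Mb of chromosome 11, RBMS2 with its pseudogene RBMS2P1, PDXDC1 with PDXDC2P and ABCC6 with ABCC6P1. Random placements of the same spans gave at most 1, and on average 0.0140, over 1000 draws, so reads shared between near-identical copies are a candidate source of these 4. The rule on symbols misses USP18 with USP41P over 2.19 Mb of chromosome 22, also genes of the same family, and for the remaining clusters, such as FOSL2 with a bin 5.74 Mb away on stiff alone, copies and true contacts cannot be told apart by gene names. No biological explanation was tested.

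Many more calls on 1 surface were found at some genes, and 80 differed by at least 4. In 57 the difference came from several clusters, none of which differed by 4 alone, and random swaps of the surface labels, cluster by cluster, gave 50.3 such genes on average (38 to 64, central 95% of 1000 swaps), which is consistent with clusters of a gene that differ independently of each other. The swaps say nothing about the other 23, VIM, KLF6 and BOD1 among them, where 1 cluster differed by at least 4. Calls near the threshold and stiffness itself stay open, because the score belongs to a cluster, can be ranked only within its list and has no replicate.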
